A study of Mus musculus with 2 samples.

How the data were processed

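RNA was sequenced from mouse CD4+ T cells of wild-type C57BL/6 mice aged 6 to 8 weeks. The cells had been cultured for 48 h under conditions that drive T helper 17 (Th17) differentiation. They were grown with antigen presenting cells (APCs) that were either wild type (WT) or transgenic for OX40L (OX40L-TG), the ligand of the T cell costimulatory receptor OX40. Per the labels' protocols, RNA was taken from the cultured cells, and 1 µg of total RNA went into an Illumina TruSeq library. There was 1 library per condition, called here the WT-APC library and the OX40L-TG-APC library.

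The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the size of the library) for each gene in both libraries. Reads were aligned with TopHat2 and values were made with Cuffdiff on the mouse build mm9, per the submitters' processing notes. Versions, gene models, strand handling and filters were not given in the sources used here. A further table deposited by the authors holds their comparison of the libraries, with the log2 of the FPKM ratio and a p-value per listed gene, per the file headers. It has no q-value column, and each of its 398 rows has an absolute log2 ratio of at least 1 and a p-value under 0.05. Its WT-APC FPKM were 0.976 times those of the full table for 376 of the 398 genes and equal to them for the other 22, within 0.2%. Its OX40L-TG-APC values were at a median of 0.999 times those of the full table. Log2 ratios lay a median of 0.033 higher in the comparison table than in the full table, though not for the 22 genes with equal WT-APC values, and the values below come from the full table unless the authors' comparison is named.

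The full table holds 24440 features. Of these, 13056 carry an Entrez gene identifier, 6666 carry XLOC identifiers, which transcript assembly gives to loci, and 4718 carry identifiers that start with n and are not explained in the file. Symbols and gene classes came from an NCBI RefSeq gene table of assembly GRCm38, which held 13030 of the 13056 Entrez identifiers. For 99.8% of these the printed locus overlapped the GRCm38 gene, and for 43.2% the start agreed within 1 bp. The printed coordinates thus follow GRCm38 although the processing notes name mm9, and they are given as the authors' table prints them. A locus spans the whole gene, exons and introns together, and sometimes several merged genes. Gene counts and lists used the genes with Entrez identifiers, and the other features are described separately.

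Depth was not stated. A low FPKM value of a gene with a single transcript steps in units of 1 fragment, and these steps were compared between libraries over 263 such genes with values under 0.3 FPKM and transcripts of at least 1500 bases. The ratio of the steps was 0.873, and 53.6% of the genes had whole-number fragment ratios at it within 0.2%, against 2.27% at a shifted ratio. This gave about 24700000 fragments for the WT-APC library and 28300000 for the OX40L-TG-APC library, a depth ratio of 1.15. On simulated fragments of 5286 genes the procedure returned the depth ratio with an error of 0% and the library sizes with an error of 5.48%. The simulated libraries had the same gene lengths and no scaling beyond library size, so the exact ratio followed from their design. The simulation checks the arithmetic and not the depths estimated here. Fragments per gene were estimated from the estimated library sizes and the median length of the gene's annotated transcripts. No correction for fragment length was made, so the fragment numbers and intervals of short genes are rough. Each ratio has a 95% exact Clopper-Pearson interval from these fragment numbers. Such an interval covers counting error only, and not the variation between cultures or animals.

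Because each condition had 1 library, no test between conditions, standard error or p-value was computed. Change was expressed as log2((OX40L-TG-APC FPKM + 1)/(WT-APC FPKM + 1)), which understates the ratio of low genes. Genes whose larger value was under 1 FPKM were left out. A gene counted as higher or lower when this change reached 2-fold. Before the data were examined, 45 gene lists were fixed, 32 of programmes and pathways and 13 of cell types, with 725 entries for 694 genes, of which 699 entries were found in the table. The median change of a list was placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins. A list stood apart when its percentile lay under 2.5 or over 97.5, and lists with under 5 kept members received no percentile. On simulated fragments of 9372 genes for the OX40L-TG-APC against WT-APC comparison, with a gene-to-gene spread of 0.35 log2, 5 of 5 lists raised 1.5-fold and 5 of 5 raised 2.83-fold stood apart. Of 50 unchanged lists 1 stood apart. Of 100 genes raised 2.83-fold, 85 reached 2-fold, as did 21 of 9172 unchanged genes.

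Named genes were chosen by a rule set before the data were examined. It took 14 genes tied to the question, the 8 highest and 8 lowest changes among genes with a larger value of at least 5 FPKM, and the members of each list with the largest changes. Further list members named below, such as Bcl6 or Atf4, were chosen for their known role after the values were seen. Small RNAs and genes listed at 0 filled most of the highest ranks, so the 16 highest and 16 lowest protein-coding genes with values above 0 in both libraries were added after the values were seen. Foxp3, among the 14, was not analysed here. Some genes that the rule names are not reported here, though counts and list medians include them. Alternatives covered the pseudocount, the filter, the scaling, duplicate symbols, the random lists and the size threshold. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.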

Results

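The transcriptomes of CD4+ T cells cultured for 48 h under Th17 conditions with WT APCs or with OX40L-TG APCs were compared. The design asks which transcripts of developing Th17 cells differ when the APCs carry the OX40L transgene. Each condition was represented by 1 library, so no difference below has a replicate check, and every statement compares these 2 libraries, not the conditions. The libraries held an estimated 24700000 (WT-APC) and 28300000 (OX40L-TG-APC) fragments. Ratios are given with 95% exact intervals for counting error only.

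Il17a and Il17f, signature cytokine genes of Th17 cells, were far lower in the OX40L-TG-APC library, and Il9, the signature cytokine gene of Th9 cells, was far higher. Across 10645 annotated genes with at least 1 FPKM in either library, 241 (2.26%) were at least 2-fold higher with OX40L-TG APCs and 141 (1.32%) were at least 2-fold lower. Of these, 220 and 135 were protein-coding, and 29 and 11 differed at least 4-fold on the log2(FPKM + 1) scale. The counts include 9 higher and 3 lower genes listed at 0 in 1 of the libraries. Genes of cholesterol synthesis, of the integrated stress response and of glycolysis were higher as groups. Th17, follicular helper, lymph node homing and B cell genes were lower as groups. Of 37 fixed lists with enough members, 15 stood apart from matched random lists. For lists of genes drawn at random 1.85 would, but genes of the same programme can vary together and some lists share genes. That number is therefore no chance rate for these lists. The median log2 change of all genes was 0.11, and it was 0.0033 when the median ratio of well-expressed genes was set to 0. That scaling gave 193 higher and 173 lower genes, so that 52.7% of the calls were higher instead of 63.1%.

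**Figure D1:**
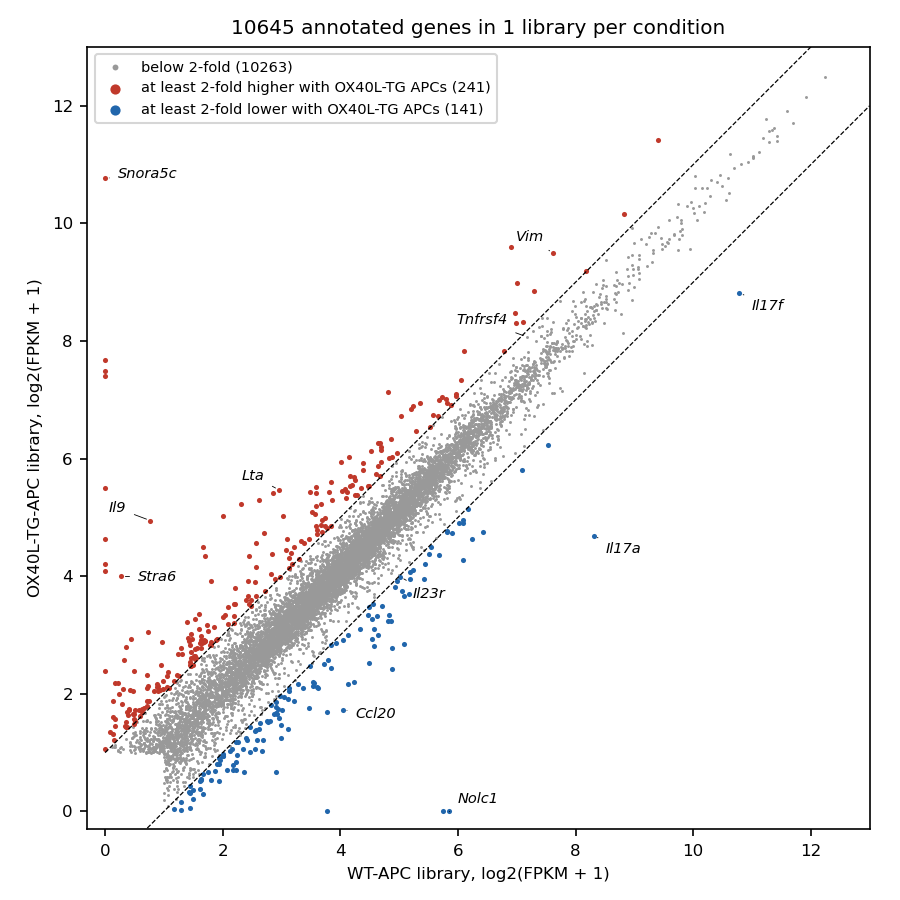
Log2(FPKM + 1) of 10645 annotated genes in the WT-APC library (horizontal axis) and the OX40L-TG-APC library (vertical axis), with 1 point per gene and dashed lines at a 2-fold difference. The 241 genes in red lie at least 2-fold higher and the 141 in blue at least 2-fold lower with OX40L-TG APCs, with Il17a and Il17f among the lower and Il9 among the higher ones.

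Tnfsf4, which encodes OX40L, was low in both libraries. Its FPKM was 2.70 with WT APCs and 2.14 with OX40L-TG APCs, and the interval of the ratio (0.610 to 1.03) included 1. The RNA came from the T cell cultures, whose share of APC RNA is not known, so this level cannot decide whether the APCs carried the transgene. It did not show the higher value that carried-over OX40L-TG APCs could give. Tnfrsf4, the gene of the receptor OX40, stood at 144 and 267 FPKM, a ratio of 1.86 (1.79 to 1.93).

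Il17a (Entrez 16171, chromosome 1, 20730904 to 20734496) encodes the signature cytokine of Th17 cells. It was 12.8-fold lower with OX40L-TG APCs (11.9 to 13.7), at 24.7 against 315 FPKM. The authors' deposited table gave a log2 ratio of -3.64 for it, with a p-value of 5e-05 that compares the libraries. The neighbouring Il17f (Entrez 257630, chromosome 1, 20777145 to 20784270) stood at 450 against 1764 FPKM, 3.92-fold lower (3.85 to 3.99). Il23r, the receptor gene for the Th17-sustaining cytokine IL-23 (chromosome 6, 67422931 to 67491855), was 2.11-fold lower (1.95 to 2.28), at 14.9 against 31.4 FPKM, though with a pseudocount of 5 its log2 change was -0.87, short of 2-fold. The transcription factor gene Rora was lower by less, at 40.7 against 66.3 FPKM, a ratio of 0.614 (0.597 to 0.632).

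Of the 21 kept members of the Th17 list, 6 were at least 2-fold lower, 2 were at least 2-fold higher and 13 were neither. The list median was -0.35, at percentile 0 of matched random lists, whose central 95% spanned 0.06 to 0.29. B cell markers (median -0.89) and MHC class II genes (-0.56) were lower in the same library, as given below. Beside Il17a, Il17f and Il23r, the lower members were Ccl20, a chemokine gene (15.5 to 2.31 FPKM, WT to OX40L-TG), the transcription factor gene Maf (184 to 74.3 FPKM) and Il10 (36.7 to 16.3 FPKM). The locus printed for Ccl20 holds another gene as well. The higher members were the cytokine genes Il24 (0.229 to 3.25 FPKM) and Il22 (2.46 to 6.16 FPKM). With a pseudocount of 5 these 2 and Il10 also fell short of 2-fold, with log2 changes of 0.66 for Il24, 0.58 for Il22 and -0.97 for Il10, and Il22 came to 0.94 with the median ratio set to 0 and to 0.98 with the totals set equal at that of the WT-APC library. Il21 (134 to 191 FPKM) and Stat3 (159 to 254 FPKM) were higher by less than 2-fold.

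Il9 (chromosome 13, 56479276 to 56482246) stood at 29.8 FPKM with OX40L-TG APCs and 0.706 FPKM with WT APCs. The ratio was 42.2 with an interval of 22.9 to 96.7, since about 9 fragments were behind the lower value. In the authors' deposited table its log2 ratio was 5.43 with a p-value of 0.0416. Other Th9 genes did not follow as a group. Of 11 kept members only Il9 and Id3 (17.7 to 50.4 FPKM) were at least 2-fold higher and none was lower. The median of 0.24 lay at percentile 84.6, whereas the mean of 0.54, which Il9 and Id3 raise, lay at percentile 98.3. Spi1, which encodes the Th9 factor PU.1 and is also a myeloid and B cell gene, stood at 0.938 against 2.83 FPKM.

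Ifng, the signature Th1 cytokine gene, was low in both libraries (1.46 and 1.78 FPKM), and the interval of its ratio (0.808 to 1.83) included 1. Th1, Th2 and Treg lists lay inside the range of random lists. In the Th1 list 1 of 15 members was higher (Il12rb2, 12.7 to 27.2 FPKM) and 1 was lower, with a median of 0.17 and a mean of -0.03. In the Th2 list 2 of 8 were higher, the chemokine receptor genes Ccr4 (9.43 to 22.7 FPKM) and Ccr8 (12.4 to 30.9 FPKM), with a median of 0.25. Among 15 Treg genes, Tnfrsf18 (126 to 314 FPKM) and Ikzf4 (2.69 to 6.54 FPKM) were at least 2-fold higher and 1 was lower, with a median of 0.12.

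**Figure D2:**
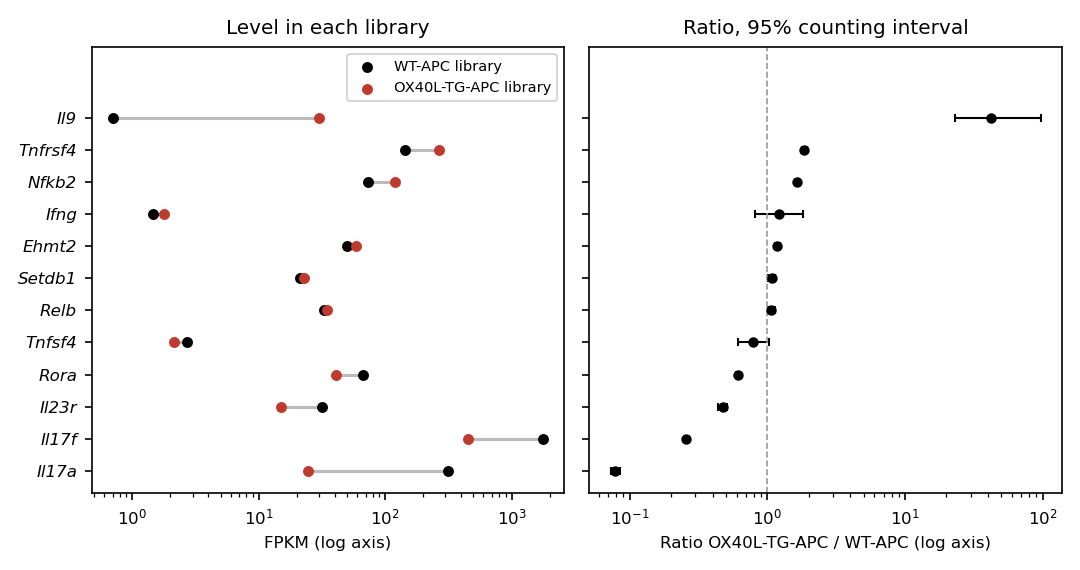
FPKM of 12 genes fixed beforehand in each library on a log axis (left, 1 point per library) and the ratio of OX40L-TG-APC to WT-APC on a log axis with its 95% exact counting interval as a bar (right, dashed line at 1). Il17a, at 315 and 24.7 FPKM, and Il9, at 0.706 and 29.8 FPKM, lie farthest from a ratio of 1, and the bars of Tnfsf4 and Ifng cross it.

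Genes of the NF-kB pathway and of chromatin repression differed little as groups. None of 23 NF-kB subunit and regulator genes reached 2-fold, and their median of 0.11 lay at percentile 38.6. Nfkb2, which encodes the non-canonical subunit p100/p52, stood at 120 against 72.9 FPKM, a ratio of 1.65 (1.60 to 1.71). Its partner Relb stood at 35.0 and 32.7 FPKM. Ehmt2, which encodes the H3K9 methyltransferase G9a, stood at 59.4 against 50.3 FPKM, a ratio of 1.18 (1.14 to 1.23), and Setdb1, another H3K9 methyltransferase gene, at 22.8 and 21.2 FPKM. The log2 change of Ehmt2, 0.24, was close to the median of the list of housekeeping references, 0.22. The log2 changes of Relb and Setdb1 were both 0.10 and turned to -0.02 with the median ratio set to 0, and the loci printed for both hold other genes too. The 20 genes of H3K9 methylation and heterochromatin (median 0.16), 18 polycomb genes (0.22) and 19 histone deacetylase and co-repressor genes (0.12) held none at 2-fold, and these 3 lists lay inside the random range. Jarid2, a polycomb cofactor gene, had the largest change among them (19.3 to 36.8 FPKM).

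Genes of the TNF receptor superfamily moved apart. Tnfrsf9 (5.49 to 25.7 FPKM), which encodes 4-1BB, and Tnfrsf18, which encodes GITR, were at least 2-fold higher, while Tnfrsf8 (22.2 to 8.61 FPKM) and the B cell receptor gene Tnfrsf13c (6.49 to 2.44 FPKM) were at least 2-fold lower. The locus printed for Tnfrsf9 holds 6 genes. The median over 15 kept members was -0.09, at percentile 0.12, but their mean was 0.047, at percentile 18.6. B cell markers were lower in the same library, as given below. The list of TNF superfamily ligands stood apart as higher by its median of 0.41, at percentile 99.5. Of its 10 kept members 6 lay above the median of all genes, none was at least 2-fold lower and 3 were at least 2-fold higher. These were Lta, which encodes lymphotoxin alpha (6.78 to 43.2 FPKM), Tnfsf11, which encodes RANKL (1.74 to 7.08 FPKM), and Tnfsf14 (4.37 to 11.6 FPKM). Ltb stood at 335 against 170 FPKM. Without the filter on low values the ligand median was 0.11, at percentile 79.3.

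Among 12 other cytokine genes, Il2 (4.48 to 19.4 FPKM) and Tgfb3 (2.34 to 8.04 FPKM) were at least 2-fold higher and Spp1 (1.81 to 0.291 FPKM) was lower. Their median of 0.38 lay at percentile 99.4, and without the filter it was -0.068, at percentile 2.39. Of 24 cytokine receptor genes 3 were higher and none lower, with a median of 0.12 inside the random range. They were Il7r (13.3 to 47.8 FPKM), Il10ra (4.28 to 11.1 FPKM) and Il12rb2. JAK-STAT feedback genes had a median of 0.00 at percentile 3.49, and Cish (24.9 to 60.7 FPKM) and Socs2 (11.1 to 25.4 FPKM), targets of STAT5, were the 2 of 13 that were higher.

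Genes of cholesterol biosynthesis and uptake were higher as a group. All 21 lay above the median of all genes, 10 were at least 2-fold higher and none was lower. The list median was 0.92, at percentile 100, against a random range of 0.02 to 0.24. Fdps (13.5 to 38.4 FPKM), Lss (18.03 to 48.5 FPKM), Mvd (17.3 to 46.1 FPKM) and Acat2 (11.7 to 28.3 FPKM), enzymes of the pathway, had the largest changes.

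In the list of the integrated stress response and the unfolded protein response, 6 of 19 members were at least 2-fold higher and none lower, with a median of 0.58 at percentile 100. Atf3 (0.410 to 4.21 FPKM), Asns, which encodes asparagine synthetase (4.91 to 16.8 FPKM), Trib3 (2.11 to 6.87 FPKM) and Vldlr (1.75 to 5.08 FPKM) changed most. Atf4, the transcription factor gene at the centre of the response, stood at 187 against 126 FPKM. The chaperone gene Hspa5, a marker of the unfolded protein arm, stood at 254 and 251 FPKM.

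Of 22 genes of glycolysis and the hypoxia response, 19 lay above the median of all genes, 2 were at least 2-fold higher and none was lower. Those were the glucose transporter gene Slc2a3 (67.4 to 228 FPKM) and Ero1a (40.1 to 123 FPKM). The median of 0.45 lay at percentile 99.98, and the mean of 0.54 at percentile 96.5. The lists of oxidative phosphorylation (median 0.24, 23 genes) and cytosolic ribosomal proteins (0.11, 25 genes) lay inside the random range with no member at 2-fold. Cell cycle genes were slightly higher as groups without any member at 2-fold. The 20 G2/M genes had a median of 0.32, at percentile 99.6, and all 20 lay above the median of all genes. The 20 G1/S genes had a median of 0.30, at percentile 99.2. With means instead of medians these percentiles were 93.8 and 83.4.

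**Figure D3:**
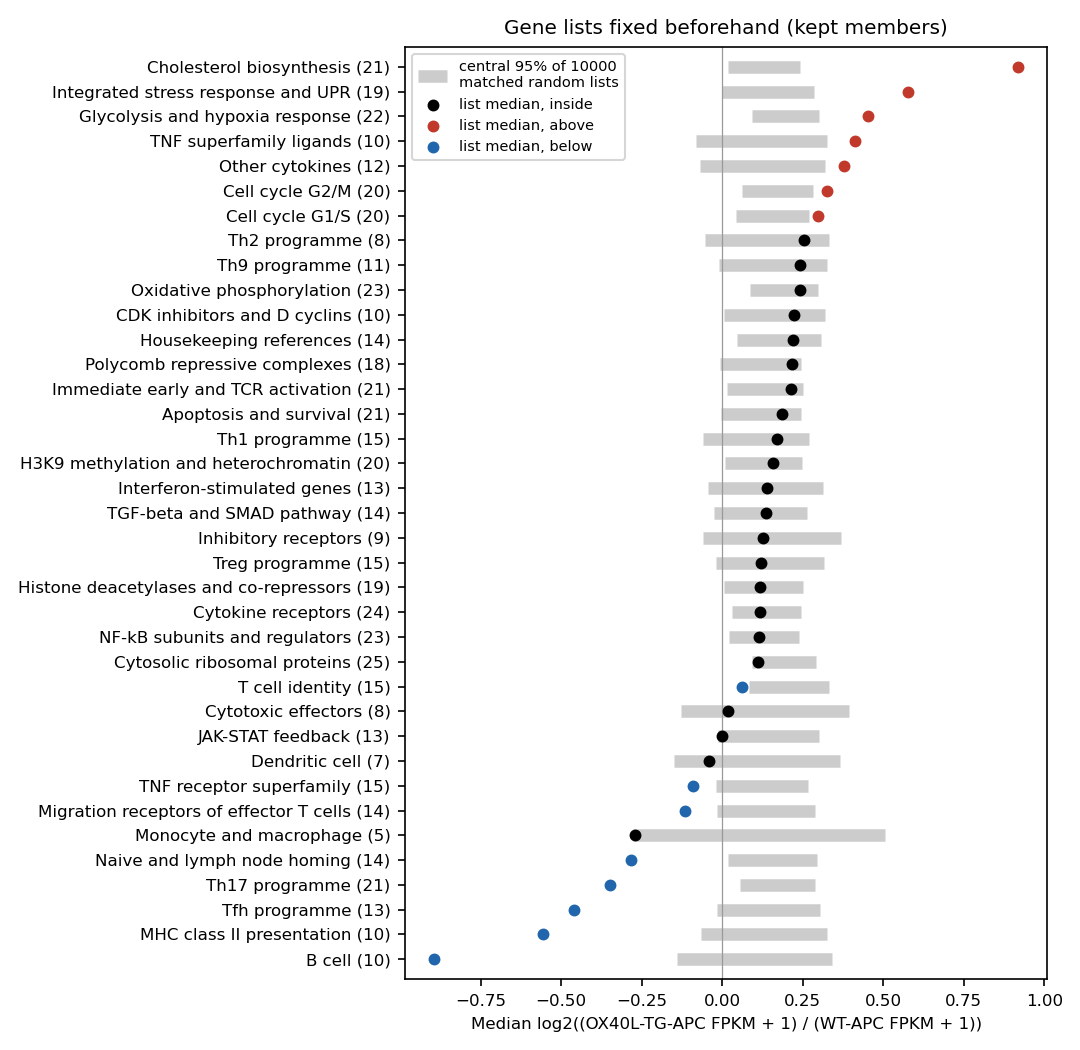
Median log2 change of 37 gene lists fixed beforehand (points; number of kept members in parentheses) with the central 95% of 10000 expression-matched random lists as grey bars. Of the lists, 7 lie above the bars, led by cholesterol biosynthesis at 0.92, and 8 below, led by B cell markers at -0.89. Of 37 lists of genes drawn at random, 1.85 would stand apart.

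Follicular helper (Tfh) genes were lower as a group. Of 13 kept members 4 were at least 2-fold lower and none higher, with a median of -0.46 at percentile 0. They were Pou2af1 (33.0 to 6.21 FPKM), Slamf6 (27.97 to 8.45 FPKM), the costimulatory receptor gene Icos (67.0 to 30.1 FPKM) and Tox (6.54 to 2.61 FPKM). Bcl6, the gene of the lineage factor, stood at 10.01 against 18.6 FPKM. Pou2af1, Bcl6 and Cxcr5 are also genes of B cells, and B cell markers were lower in the same library. All 10 kept B cell markers lay below the median of all genes and 4 were at least 2-fold lower, with a median of -0.89 at percentile 0. Cd79a stood at 2.20 against 6.52 FPKM. The plain ratios of the 10 markers ran from 0.223 to 0.547 with a median of 0.407.

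MHC class II genes, which B cells and other APCs express, had a median of -0.56 at percentile 0, with 3 of 10 at least 2-fold lower. These were H2-Aa (58.8 to 25.5 FPKM), H2-Eb1 (29.6 to 13.1 FPKM) and the transactivator gene Ciita (3.69 to 1.27 FPKM). H2-Ab1 hardly differed (92.7 to 98.9 FPKM), and H2-Oa was at least 2-fold higher (6.15 to 19.9 FPKM). In the monocyte and macrophage list Lyz2 (4.55 to 1.01 FPKM) and Tyrobp (2.87 to 0.827 FPKM) were the 2 of 5 that were lower, and the median of -0.27 lay at percentile 2.66. Dendritic cell markers had a median of -0.04 and a mean of 0.19, inside the random range. In that list Flt3 (3.46 to 1.09 FPKM) and Cd86 (13.4 to 6.07 FPKM) were lower, and Batf3, a transcription factor gene also used by activated T cells, was higher (2.18 to 21.5 FPKM), at a printed locus that holds 3 genes.

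T cell identity genes held no member at 2-fold among 15, with a median of 0.063 at percentile 1.00 and a mean of 0.15 at percentile 23.5. Against unmatched random lists the median lay at percentile 24.8, and it turned to -0.01 with equal totals and to -0.06 with the median ratio set to 0. Cd3e stood at 86.5 and 98.0 FPKM, Cd4 at 246 and 201 FPKM and Cd28 at 142 and 217 FPKM, OX40L-TG first. The other cell type lists had under 5 kept members. Plasma cell (median 0.09, mean -0.09, 4 genes), CD8 T cell (-0.16, 2 genes) and natural killer cell lists (-0.28, 4 genes) and the mast cell and basophil gene Kit (-0.35) held none at 2-fold. Lower by at least 2-fold were S100a8 of the neutrophil list (2.81 to 0.888 FPKM; list median -0.64, 2 genes), Blk as the kept gamma delta T cell gene, which B cells share (-1.13), and Pecam1 as the kept stromal and endothelial gene (22.7 to 7.55 FPKM, -1.47). Haemoglobin genes went both ways (list median 0.49, 4 genes).

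Genes of naive T cells and of homing to lymph nodes were lower as a group, with 3 of 14 at least 2-fold lower, 1 higher and a median of -0.28 at percentile 0. Foxp1 (19.3 to 7.63 FPKM) and S1pr1 (55.6 to 26.1 FPKM) were among the lower ones, and Il7r was the higher one. Migration receptor genes of effector T cells had a median of -0.12 at percentile 0.10, with 4 of 14 at least 2-fold lower and none higher. Among them were the chemokine receptor genes Ccr1 (2.83 to 0.758 FPKM) and Ccr2 (4.53 to 1.71 FPKM), which monocytes also express, and the gut homing receptor gene Gpr15 (14.2 to 6.29 FPKM). The lower B cell and myeloid markers of the same library stand beside these lists too.

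**Figure D4:**
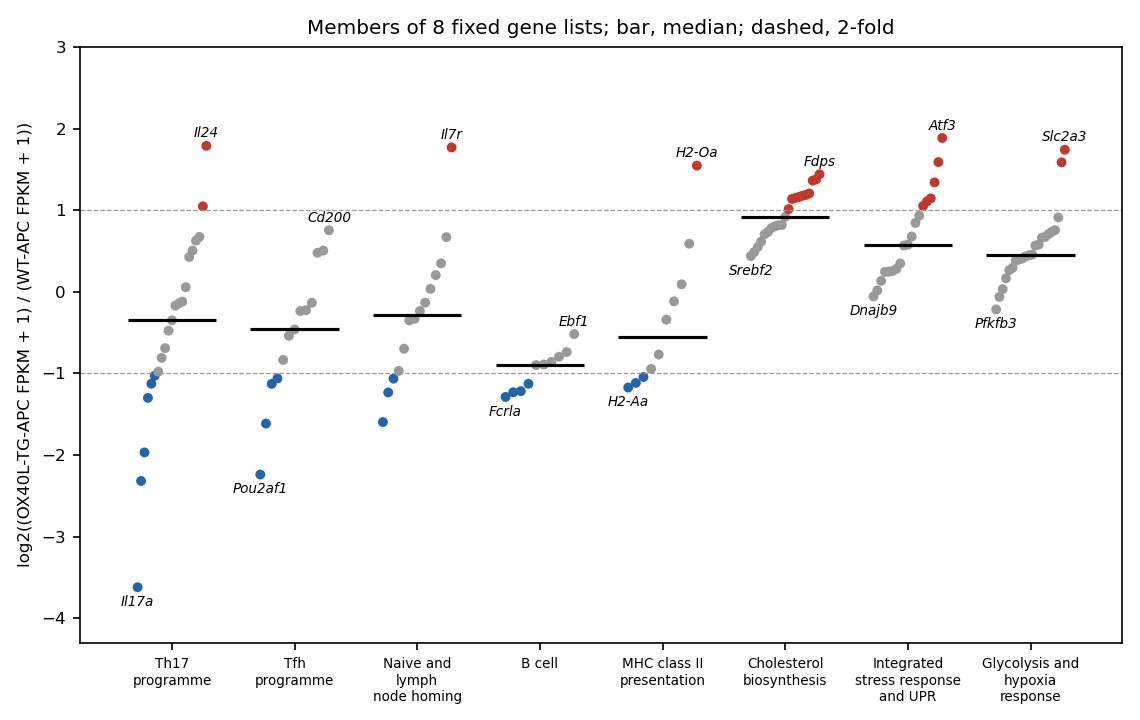
Log2((OX40L-TG-APC FPKM + 1)/(WT-APC FPKM + 1)) of the kept members of 8 lists (1 point per gene, black bars at list medians, dashed lines at 2-fold, red and blue for members at least 2-fold higher and lower). Cholesterol biosynthesis holds 10 red points and no blue ones, and the Th17 list runs from Il17a at -3.62 to Il24 at 1.79.

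The remaining lists lay inside the random range. Among 21 apoptosis and survival genes (median 0.19), 2 were at least 2-fold higher, among them Bcl2, which encodes a survival protein (15.4 to 42.8 FPKM). The genes of the death-promoting Bcl2l11 (23.9 to 7.05 FPKM) and of Bcl2a1d (45.5 to 21.6 FPKM), which has near-identical copies and is uncertain for that reason, were lower. Of 10 genes of CDK inhibitors and D cyclins (median 0.22) Cdkn1a was higher (11.1 to 44.7 FPKM). In the TGF-beta list of 14 (median 0.14), 3 were higher, Id1 (0.394 to 3.12 FPKM) and Id3 among them. Among 21 immediate early genes (median 0.21), 4 were higher, with Ier3 (15.1 to 60.5 FPKM) and Dusp5 (19.8 to 60.1 FPKM) leading, and Dusp6 (27.5 to 9.08 FPKM) was lower. Interferon-stimulated genes (median 0.14, 13 genes), inhibitory receptors (0.13, 9 genes), cytotoxic effectors (0.02, 8 genes) and housekeeping references (0.22, 14 genes) had no member at 2-fold.

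Over all genes, the lowest protein-coding ones with values in both libraries included, after Il17a, the protease inhibitor gene Serpinb1a (6.56-fold lower, 5.72 to 7.58), Ccl20 (6.71-fold, 4.98 to 9.17), Prss12 (11.1-fold, 8.13 to 15.6, at a locus of 2 genes) and Pou2af1 (5.32-fold, 4.81 to 5.91). Atp6v0d2, which encodes a subunit of the vacuolar proton pump, was 4.86-fold lower (4.37 to 5.42), Chst2 5.67-fold (5.13 to 6.28), and Ikzf3, the gene of the transcription factor Aiolos, 3.62-fold (3.44 to 3.82). At the other end, after Il9, stood the retinol uptake receptor gene Stra6 (0.209 to 15.0 FPKM) and Selenbp1 (10.4-fold higher, 8.74 to 12.7). Tnip3 was 8.57-fold higher (6.84 to 10.8), Lmna, which encodes nuclear lamins A and C, 6.71-fold (5.96 to 7.58), and the inducible nitric oxide synthase gene Nos2 stood at 5.97 against 0.275 FPKM. Ranked by log2(FPKM + 1) over all genes, 7 of the 8 highest were small RNAs listed at 0 with WT APCs, led by Snora5c at 1741 FPKM with OX40L-TG APCs. The lowest were Nolc1 (56.8 FPKM with WT APCs), Snora34 (53.0 FPKM) and Pprc1 (12.7 FPKM), each listed at 0 with OX40L-TG APCs. Nolc1 and Pprc1 share 1 printed locus (chromosome 19, 46056538 to 46087876), and a value of 0 can be a failed estimate, so no fold is given.

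The authors' deposited table lists 398 genes, 254 as higher and 144 as lower with OX40L-TG APCs, and 37 of them have its smallest p-value, 5e-05. These p-values are unadjusted. Of the 398 genes, 385 passed the filter used here and all 385 had the same sign in both tables, which come from the same libraries. The 2-fold rule also held for 288 of them, and the other 97 fell short because 1 FPKM was added before the ratio and the tables differ in scale. Of the 382 genes at 2-fold here, 94 were not listed by the authors, 16 of them small RNAs. Prss12, Batf3 and Tnfrsf9, whose printed loci are shared with other genes, were also among the unlisted ones, though Ccl20 at such a locus was listed. There, 9 cholesterol biosynthesis genes were listed as higher and none as lower, and 6 Th17 genes were listed as lower and none as higher.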

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

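The tests of 1 scale factor, of counting error, of exchanged labels and of the Tfh members were chosen after the values they rest on had been seen.

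The XLOC loci and the features with n identifiers entered no comparison above, and 146 of the 5097 kept ones were at least 2-fold higher with OX40L-TG APCs, against 910 that were lower. Feature n265639 at the start of the chromosome 9 sequence (3000192 to 3168181) was listed at 370.4 FPKM with OX40L-TG APCs and at 0 with WT APCs. All 9 kept features printed at that locus were listed at 0 with WT APCs, and they summed to 603 FPKM with OX40L-TG APCs. A value of 0 can be a failed estimate, which was not tested here. These values are therefore not read as a difference in transcript level.

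Among these features, 889 of the 3388 kept XLOC loci were at least 2-fold lower with OX40L-TG APCs and 123 were higher, and their share of all FPKM was 15.4% with WT APCs and 9.51% with OX40L-TG APCs. A common scale factor would move them with the annotated genes, but their median log2 change lay lower by a difference of -0.51. It was -0.39 for the 666 with a further identifier attached and -0.40 for the other 2722. More genomic DNA in the WT-APC library would also raise barely expressed genes there, and the log2 ratio of such protein-coding genes differed from that of well-expressed ones by only -0.058. Unspliced RNA comes from transcribed genes and need not raise barely expressed ones, so this difference cannot decide about unspliced RNA. Counting noise in low features stays open: a test set beforehand, on features with a mean of at least 5 FPKM, gave a difference of -0.16 that lay between its bounds. Of the kept loci 526 were at 0 in the OX40L-TG-APC library and 37 in the other, which noise would also give if the loci had been assembled mainly from WT-APC reads. Whether they were, whether the zeros are failed estimates, and a difference between the conditions were not tested.

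The lower levels of Il17a, Il17f and Il23r were set against 3 technical explanations. A much smaller share of T cell RNA in the OX40L-TG-APC library would lower T cell genes together. The median of the T cell identity list was 0.063, at percentile 1.00 of matched random lists, with no member at 2-fold. FPKM values are shares of a library, so the number of T cells in the culture was not tested. Counting error alone would leave the ratios near 1, and the highest upper bound of the 3 ratios was 0.512. Exchanged labels cannot be told apart from a true difference, because Tnfsf4, which could mark carried-over OX40L-TG APCs, differed by only -0.24 on the log2 scale at about 112 to 123 fragments. An effect of the OX40L-TG APCs stays a hypothesis, since with 1 culture per condition it cannot be separated from a chance difference between cultures.

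The lower Tfh genes came with lower B cell markers, so fewer carried-over B cells in the OX40L-TG-APC library could contribute. Of the abundant APC transcripts, Cd74 stood at 172 FPKM with WT APCs and 89.2 FPKM with OX40L-TG APCs and H2-Aa at 58.8 and 25.5 FPKM, but H2-Ab1 stood at 92.7 and 98.9 FPKM, so they did not all fall together. The labels name no sort after culture. The members taken as not highly expressed by B cells were Icos, Tox, Pdcd1, Tox2, Tcf7, Sh2d1a and Il21. These 7 had a median of -0.46, the value of Tox2, at percentile 0.01, though Il21 was higher by less than 2-fold. They were picked after the values were seen from a list already at percentile 0, and their levels in B cells were not measured. The percentile therefore does not decide how much B cells contributed. Of the other 6 members, Btla (79.3 to 111 FPKM, WT to OX40L-TG) and Cd200 (31.8 to 54.2 FPKM) were higher as well, also by less than 2-fold. For the lower ones, Pou2af1, Slamf6, Bcl6 and Cxcr5, the explanation stays open too. A difference in the T cells between the conditions stays open as well.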

How the results depend on the processing

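No paired analysis was possible because each condition had 1 library and no result came from a test. The authors' table gave no q-value, so the planned count at q under 0.05 was not run. Restriction to protein-coding genes or to genes above 0, the inclusion of all features and equal totals at the WT-APC total were chosen after the data were seen, as were the alternatives for Il10 and Il22. No symbol stood on several rows, so summing rows moved nothing and says nothing about stability. Of 37 lists, 25 kept their side of the random range in every alternative that left the list at least 5 members, Th17, Tfh, B cell, MHC class II, cholesterol biosynthesis and stress response among them. At 5 FPKM the B cell, dendritic cell, monocyte and macrophage and cytotoxic lists had too few and were not run. Of 199 named genes, 151 kept their side of the 2-fold threshold in every alternative run for genes and none at 2-fold changed sign; the others crossed it 44 times downwards and 11 times upwards. Where no cause is given below, it was not tested. Depth limits low genes most: about 9 fragments were behind Il9 in the WT-APC library.

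The 241 higher and 141 lower genes became 405 and 251 with a pseudocount of 0.1, and 101 and 39 with a pseudocount of 5, since a larger pseudocount shrinks low genes more. They became 767 and 360 at a 1.5-fold threshold, and 387 and 1051 with all features, which adds the XLOC loci and the features with n identifiers. The median log2 change of 0.11 became 0.13 and 0.084 with those pseudocounts, 0.089 without the filter, 0.12 at 5 FPKM, 0.047 with equal totals, 0.045 with these at the WT-APC total, 0.0033 with the median ratio set to 0 and 0.046 with all features.

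Without the filter the median of other cytokines turned from 0.38 to -0.068 and that of TNF ligands came to 0.11, inside the range, because members near 0 FPKM entered. Lists that newly stood apart there were Th2 (0.26, higher), interferon-stimulated genes (-0.070, lower) and monocytes and macrophages (-0.22, lower). The last list, of 5 genes, also stood apart lower with a pseudocount of 0.1 (-0.45), equal totals (-0.35), means (-0.54) and, at -0.27, with protein-coding genes, with genes above 0 or against unmatched lists. With a pseudocount of 5 the G1/S median came to 0.24, inside the range. Equal totals put other cytokines inside it (0.21) and CDK inhibitors and D cyclins above it (0.28). That setting also raised the values of both libraries, so that 11064 genes passed the filter and the pseudocount weighed less; at the WT-APC total no list changed its side. Against unmatched lists the T cell identity median of 0.063 lay inside. With means in place of medians the TNF receptor (0.047), other cytokine (0.34), G1/S (0.24), G2/M (0.34), glycolysis (0.54) and T cell identity (0.15) lists lay inside, and Th9 (0.54) lay above.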

Other observations

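All gene lists and genes in this part were chosen after the data were seen, so their percentiles describe patterns that were already noticed and are no test. Most genes of MHC class I antigen presentation had slightly raised values with OX40L-TG APCs, short of 2-fold. Of 21 kept members 17 lay above the median of all genes, while Tapbp (-0.40), Erap1 (-0.22) and Pdia3 (-0.06) had log2 changes below 0, and the list median of 0.44 lay at percentile 100 of matched random lists. H2-K1 stood at 813 against 506 FPKM, B2m at 1289 against 853 FPKM, Psmb9, an immunoproteasome gene, at 137 against 76.4 FPKM, and Nlrc5, the class I transactivator gene, at 16.7 against 10.04 FPKM. Of the 21 only H2-Q7 (23.8 to 75.9 FPKM) reached 2-fold, as did H2-Q10 outside the list (2.47 to 14.1 FPKM), and class I genes share reads with near-identical copies, so single values are uncertain. Interferon-stimulated genes as a list did not stand apart.

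Most genes of a list known to be induced by hypoxia lay above the median of all genes, though few reached 2-fold. This list is no separate support for the fixed list of glycolysis and the hypoxia response, with which it shares P4ha1, Pdk1, Bnip3 and Egln3, and Ddit4 and Kdm3a are in other fixed lists. Of 19 kept members 18 lay above the median of all genes and 5 were at least 2-fold higher, with a median of 0.77 at percentile 100. Ndrg1 (31.8 to 105 FPKM), Hilpda (35.6 to 114 FPKM), P4ha2 (7.52 to 23.8 FPKM) and Ddit4 (109 to 227 FPKM) were among them, while Hif1a itself stood at 368 against 406 FPKM. The metallothionein genes Mt1 (127 to 505 FPKM) and Mt2 (27.2 to 140 FPKM), neighbours on chromosome 8, and the intermediate filament gene Vim (195 to 720 FPKM) were higher as well. Of 8 kept annexin genes 3 were at least 2-fold higher, Anxa2 (155 to 461 FPKM), Anxa4 (7.46 to 20.7 FPKM) and Anxa6 (61.9 to 133 FPKM), with a list median of 0.48 at percentile 99.8.

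Of 5 kept targets of the aryl hydrocarbon receptor, 2 reached 2-fold. Cyp1a1 (5.14 to 1.63 FPKM) and Cyp1b1 (2.74 to 0.747 FPKM) were at least 2-fold lower, while Ahrr, at 0.638 against 1.97 FPKM, and Tiparp, at 18.8 against 26.7 FPKM, were lower by less on the log2(FPKM + 1) scale. Asb2 was higher by less than 2-fold (2.82 to 4.29 FPKM), and the list median of -0.86 lay at percentile 0.02. The receptor gene Ahr stood at 79.2 against 101 FPKM.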
